A study of Homo sapiens with 4 samples.

How the data were processed

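RNA was sequenced from WI-38 cells, an established line of human fetal lung fibroblasts that stops dividing after a limited number of population doublings. The labels give 4 libraries, with 1 library in each group: whole cells and mitoplasts from young cells at population doubling level 21, and whole cells and mitoplasts from senescent cells at level 60. Mitoplasts are mitochondria stripped of their outer membrane; per the labels' protocols, cells were lysed with CHAPS, crude mitochondria were swollen in hypotonic buffer and treated with RNase A before and after the mitoplast pellet was collected, which digests RNA outside the inner membrane. Libraries were made with a TruSeq RNA kit, per the labels. Reads from a gene and an overlapping antisense gene are treated here as impossible to tell apart, because the strand setting is not given in the sources used here.

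The deposited values are FPKM, fragments per kilobase of transcript scaled to mapped fragments, per the file headers. Each of the 4 files lists 393483 transcripts of a merged set with an FPKM value per library. The submitters' processing notes name TopHat2 2.0.14, Cufflinks 2.2.1, Cuffdiff and the genome build hg19, without their order or role. The annotation release and the normalization options are not given in the sources used here. The files hold no counts, transcript lengths, coordinates or confidence intervals, so the depth of each library is unknown and no counting error can be given.

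Of the transcripts, 185591 carry an Ensembl identifier and 207892 are assembled transcripts without a name. Identifiers were matched to current symbols through a table of gene identifiers and GENCODE release 29, which was used for names, types and transcript lengths and not for coordinates, since its build differs from that of the files. A symbol was found for 94.1% of annotated transcripts, which gave 51052 symbols. Annotated transcripts with no symbol held between 11.4% and 22.5% of the annotated FPKM of a library. A gene's value was the sum of its annotated transcripts and of assembled transcripts in a locus that holds that gene alone in the given library. An assembled transcript in a locus that holds several genes, called spanning below, was given to none of them. Which of those genes it covers is not known. Assembled transcripts held 53.7% of the summed FPKM in young whole cells, 76.2% in senescent whole cells, 92.7% in the young mitoplast library and 97.3% in the senescent mitoplast library. Exact zeros can be failed or reassigned estimates: of 2077 coding genes at 50 FPKM or more in young whole cells, 9.87% were listed at 0 in the senescent mitoplast library. Such genes are described as listed at 0.

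Ratios are log2((A + 1)/(B + 1)) of FPKM, which understates the change of low genes. Genes at 5 FPKM or more in at least 1 of the libraries compared were counted at a ratio of 1 or more in either direction between ages and 2 or more between fractions. For the difference of the fraction ratios between ages, each ratio was centred on its median over nuclear-encoded genes, and genes at 5 FPKM or more in both libraries of a fraction were counted at a difference of 2 or more. Each comparison sets 1 library against 1, so no p-value or standard error is given. An additive model of age and fraction, whose residual is the difference of the fraction ratios between ages, was not fitted. A list was described by the median ratio of members at 1 FPKM or more in a library, by the members past a ratio of 1, and by the percentile of that median among 10000 random lists matched on mean expression in 20 bins. The percentile describes these libraries and is not a test between conditions.

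The gene lists, the rule for the genes named and the first set of alternatives below were fixed before the data were examined. The rule takes a set of senescence markers, noncoding RNAs, housekeeping genes and all mitochondrial mRNAs and rRNAs; the 12 highest and 12 lowest ratios per comparison among genes at 10 FPKM or more with an estimate above 0 in both libraries, outside loci with a spanning assembled transcript, without small RNAs, clone names or pseudogenes; the 8 highest and 8 lowest differences of the fraction ratios; and up to 4 list members with the largest ratio. XIST and Y-linked genes were left out. The rule asked for a valid estimate, and that this means above 0 and outside such loci was settled after the files were seen. Where an example had an estimate of 0 in a library compared, another example is given in its place or the 0 is stated. RN7SL1, in the rule, is not analysed here, and some genes that the rule selects are not reported here.

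The first set of alternatives was a pseudocount of 0.1, a filter of 1 FPKM or none, 3 rescalings, counts and mitochondrial shares without small RNA classes, list members at 5 FPKM or more, shares weighted by transcript length, and the authors' intervals, which the files do not hold. Added after seeing the data were annotated transcripts alone, protein-coding transcripts alone, a filter of 20 FPKM, and genes above 0 in each library compared outside shared loci. The list percentile was tested on simulated data built on young whole cells with noise of 0.7 (log2 SD) over 13677 genes: of 100 lists with a planted shift of 0.5, 79% lay above the 97.5th percentile of random lists, and of 100 with no shift 1% did. That simulation had independent noise and no zeros, and its recovery was not shown for the mitoplast comparisons, where random lists can spread more widely. For the import list, their 2.5th to 97.5th percentiles were −0.55 to 0.22 in whole cells and −1.71 to 0.15 between mitoplasts. The threshold step, at a ratio of 1, recovered 200 of 200 genes changed 4-fold among 8999 simulated genes, with 0 false calls. No noise was added to those data, so this outcome was fixed by the settings and checks only the calculation. It does not cover the cutoff of 2. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.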

Results

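The transcriptomes of young and replicatively senescent WI-38 fibroblasts were measured in whole cells and in RNase-treated mitoplasts. The crossed design asks which RNAs differ with senescence and which accompany the mitochondrial interior. Each of the 4 groups held 1 library, so no difference below has a replicate check and differences between libraries cannot be separated from differences between conditions. Coding genes at 5 FPKM or more numbered 7804 in young whole cells, 7318 in senescent whole cells, 6583 in the young mitoplast library and 4757 in the senescent mitoplast library. The depth of the libraries is unknown.

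In whole cells, genes of cell division were lower in the senescent library. Of 44 measured mitosis genes, 41 were lower by a log2 ratio of 1 or more and 0 were higher, with a median of −2.91, below all 10000 random lists. TOP2A, the topoisomerase that untangles sister chromatids, was at 55.7 FPKM in young and 0.69 in senescent cells, mostly in a retained-intron transcript of 554 nt. PRC1 was at 83.1 and 1.88, and MKI67, a proliferation marker, at 18.1 and 0.264. Of 41 DNA replication genes, 29 were lower by 1 or more (median −1.82). Histone genes expressed during DNA synthesis had a median of −3.83, with 27 of 30 lower: H2BC10 was at 99.3 and 0.358 FPKM, H1-5 at 92.8 and 0.329, H2AC17 at 174 and 1.82 and H4C11 at 248 and 3.03. Of 14 lamina and chromatin proteins known to decline in senescence, 12 were lower (median −2.01). LMNB1, which encodes lamin B1, was at 43.1 FPKM in young cells, of which 62.2% lay in a transcript of 557 nt without a coding frame, and at 0.516 in senescent cells, and HMGB2 at 31.9 and 2.30.

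Cyclin-dependent kinase inhibitors and p53 targets, taken as 1 list of 31 measured genes, had a median of −0.13, at the 56.2th percentile, with 3 higher and 4 lower. CDKN1A, encoding p21, was at 93.7 FPKM in young and 152 in senescent cells (log2 ratio 0.69). CDKN2A, encoding p16 and p14ARF, was listed at 0 in young and at 15.6 FPKM in senescent whole cells, while the young and senescent mitoplast libraries held 65.5 and 33.5. CCNG1 was at 30.2 and 89.5 FPKM, with 51.4% of the latter in a noncoding transcript of 562 nt.

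Secreted factors differed in both directions. Of 24 growth factors and IGF-binding proteins, 10 were higher and 6 lower, with a median of 0.40 at the 99.7th percentile; IGFBP7 was at 53.1 FPKM in young and 652 in senescent cells, TGFB2 at 50.0 and 546, and VEGFA at 82.1 and 5.91. The TGFB2 value came mainly from a noncoding transcript of 405 nt. Of 15 cytokines and chemokines, 3 were higher and 7 lower (median −0.75, 3.16th percentile): TNFRSF11B was at 47.2 and 235 FPKM and CXCL12 at 12.01 and 1.08. IL6 was at 4.0 and 3.94 FPKM and CXCL8 at 3.53 and 0.882. The higher values of TNFRSF11B and CXCL8 lay mainly in retained-intron transcripts (52.9% and 76.8%). Matrix and secreted proteins of fibroblasts had a median of −0.92 (0.01th percentile), with 22 of 44 lower and 8 higher. POSTN, encoding periostin, was at 92.0 and 2.32 FPKM, FBLN1 at 156 and 5.79, PCOLCE at 126 and 5.32 and COL6A2 at 946 and 48.2. COL1A1, encoding the main collagen of fibroblast matrix, was at 1501 and 846 FPKM. Proteases and their inhibitors had a median of −0.41 (19.9th percentile); SERPINE2 was at 35.2 and 278 FPKM and MMP2 at 819 and 127, with 67.0% of the 819 in a nonsense-mediated-decay transcript of 443 nt.

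Lysosomal genes were higher as a list, with 10 of 38 higher, 2 lower and a median of 0.49 above 99.97% of random lists. ASAH1, encoding acid ceramidase, was at 13.1 and 49.5 FPKM, the latter led by a nonsense-mediated-decay transcript (48.1%). Cytosolic ribosomal proteins had a median of −0.99 with 37 of 76 lower and 0 higher. Lists of mitochondrial proteins encoded in the nucleus lay nearer 0. Oxidative phosphorylation subunits had a median of −0.41 (6.24th percentile), mitochondrial ribosomal proteins −0.43 (2.08th), protein import and chaperones −0.66 (0.67th), RNA synthesis and processing factors −0.08 (63.0th) and the tricarboxylic acid cycle −0.32 (26.4th). GRSF1, a protein of mitochondrial RNA granules, was at 6.11 and 6.33 FPKM, and PNPT1, encoding polynucleotide phosphorylase, at 5.75 and 5.14, neither led by a coding transcript in the library where it was higher. The remaining lists, glycolysis, cholesterol synthesis, interferon-stimulated genes, actin cytoskeleton, endoplasmic reticulum stress and long noncoding RNAs, had medians of −0.13, 0.15, −0.43, −0.53, −0.26 and −0.05, all between the 5.07th and 91.1th percentile. Markers of other cell types were near the floor: 4 of 14 epithelial markers and 2 of 10 endothelial markers reached 1 FPKM in a library, with medians of −0.60 and 0.95, and blood and immune markers gave no median. Between young fractions 4 of 14 blood and immune markers reached 1 FPKM, with a median of 1.56. Polymerase III and small nuclear RNAs had a median of 0.21 (97.6th percentile), with 5 of 18 higher and 3 lower.

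**Figure D1:**
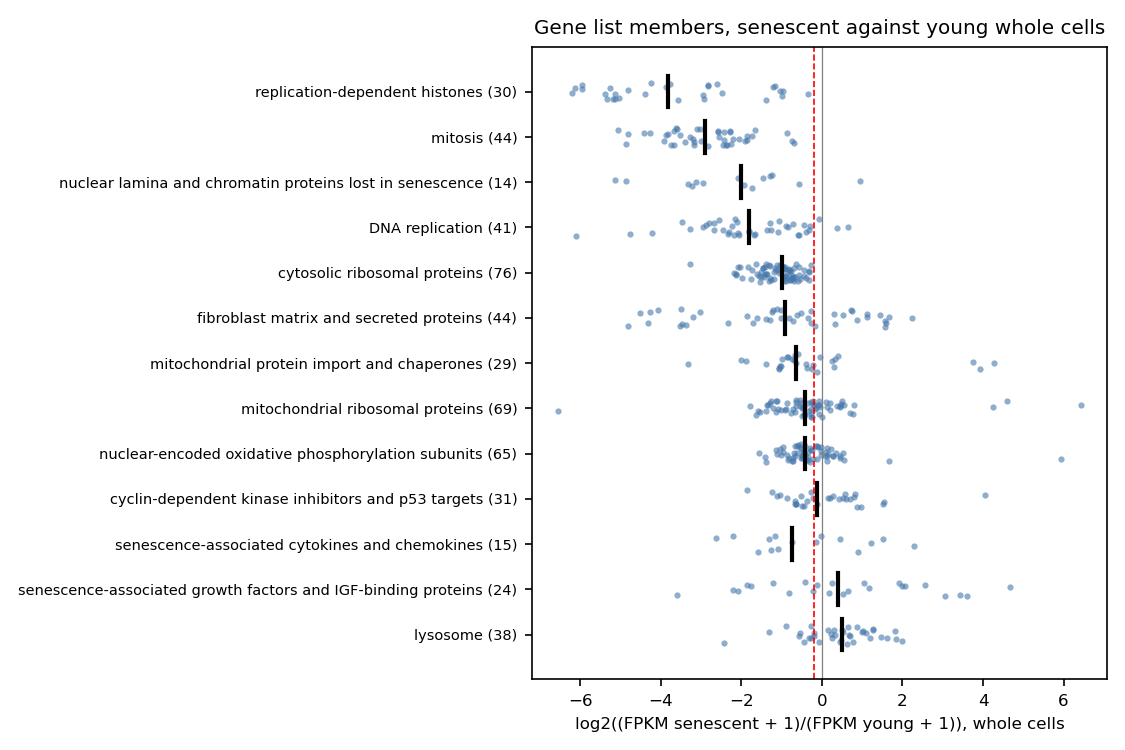
Log2 ratio of FPKM (pseudocount 1) in senescent against young whole cells, 1 library each, for the members of 13 of the gene lists. Each point is a gene, black bars are list medians, numbers in brackets are measured members, and the red dashed line is the median of all nuclear-encoded genes compared (−0.20). Of the lists plotted, those of histones and mitosis lie farthest to the left, with medians of −3.83 and −2.91.

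Across all genes, 10264 were compared, of which 1536 were higher and 2228 lower in senescent whole cells by a log2 ratio of 1 or more. Of the 10264, 347 were listed at 0 in senescent and 310 in young whole cells, and each of these passes the threshold. The median nuclear-encoded gene stood at −0.20, and relative to it the mitosis, histone and ribosomal protein lists stood at −2.71, −3.63 and −0.78. With each library rescaled to an equal sum over all genes, the split turned to 2107 higher and 1639 lower. The 12 highest ratios belonged to TMEM178B, MIPOL1, ZNF718, ANKRD1, SIM2, LIMCH1, CASC6, CHCT1, PURPL, LINC02147, MAST3 and ETFRF1. ANKRD1, encoding a cardiac ankyrin repeat protein that responds to mechanical load, was at 0.0945 FPKM in young and 57.8 in senescent cells, the latter all in its coding transcript. PURPL, a noncoding RNA known as a p53 target, was at 5.86 and 182.8 FPKM. Assembled transcripts carried the values of MIPOL1, ZNF718, SIM2, CHCT1 and MAST3, and with annotated transcripts alone ZNF718 and CHCT1 turned to −0.56 and −1.86. In TMEM178B and LIMCH1 most of the FPKM lay in noncoding transcripts of 474 and 473 nt. The 12 lowest were 9 histone genes (H2BC10, H1-5, H2AC17, H4C11, H4C2, H1-4, H2AC14, H2BC13 and H1-3) together with LRFN5, GAS2L3 and TOP2A, each of the last 3 led by a transcript without a coding frame.

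Mitoplast libraries were next compared with whole cells, to ask which RNAs were held inside the inner membrane. In young cells all 13 mitochondrial-encoded mRNAs were higher in the mitoplast library, by a median log2 ratio of 1.89. MT-CYB, encoding cytochrome b, was at 4257 FPKM in whole cells and 16952 in mitoplasts, and MT-CO1 at 8540.2 and 34115. The rRNAs MT-RNR1 and MT-RNR2 (median 2.82) were at 1853 and 4367 FPKM in whole cells and 15943 and 25273 in mitoplasts. Mitochondrial genes held 16.8% of the summed gene FPKM in young whole cells and 39.3% in young mitoplasts, but over all FPKM, assembled transcripts without a gene included, the shares ran the other way, at 7.24% and 2.64%. In senescent cells MT-CYB was at 14663 FPKM in whole cells and 29903 in mitoplasts. The other mitochondrial mRNAs, except MT-ND1 in whole cells at 13185 FPKM, were listed at 0 in both senescent libraries. There, an assembled transcript in the mitochondrial locus held 18676 and 48513 FPKM. The corresponding shares, 5.39% and 20.7%, count that transcript once and cannot be set against those of the young libraries. MT-RNR2 was listed at 0 in senescent whole cells and was at 36308 FPKM in the senescent mitoplast library. Mitochondrial tRNAs, of which 11 of 22 reached 1 FPKM in the young pair, had a median of −5.20. It turned to 3.33 for the 3 members above 0 in both libraries and outside shared loci.

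Several abundant nuclear noncoding RNAs were lower in mitoplasts of both ages, MALAT1 in senescent cells by little more than the median gene. RMRP, the RNA of the RNase MRP complex, was at 29480 FPKM in young whole cells and 1178 in young mitoplasts (log2 ratio −4.64), and at 39149.6 and 1305 in the senescent pair (−4.91). RPPH1, the RNA of RNase P, had ratios of −3.69 and −3.53. The 7SK RNA had −5.29 and −4.28, MALAT1 −3.81 and −2.18, and NEAT1, a scaffold of nuclear paraspeckles, −3.72 and −3.04. Relative to the median nuclear-encoded gene, RMRP stood at −3.97 in young and −3.08 in senescent cells, and RPPH1 at −3.02 and −1.70. On that scale 7SK stood at −4.62 and −2.46, MALAT1 at −3.14 and −0.36, and NEAT1 at −3.05 and −1.21. Each was thus less far below the median gene in the senescent pair. The list of nuclear-retained and other long noncoding RNAs had medians of −1.17 in young (11.9th percentile) and −2.36 in senescent cells (2.59th), with 2 of 15 members higher by 1 or more in each. Among these, SNHG8 was listed at 0 in young whole cells and at 73.1 FPKM in young mitoplasts, and EPB41L4A-AS1 was at 16.7 and 61.8 FPKM in the senescent pair. Polymerase III and small nuclear RNAs had medians of −4.94 in young and −7.66 in senescent cells, below all random lists. The list of noncoding RNAs discussed as mitochondrial imports holds RMRP and RPPH1, its 2 members lower by 1 or more in both ages. Of 5 measured members, 3 were higher by 1 or more in young and 1 in senescent cells. The medians, 2.33 in young and 0.78 in senescent cells, came from entries for 5S rRNA. Reads of these entries may not be told apart from those of other 5S copies. RNA5SP141 was at 30656 and 153819 FPKM in young and 23623 and 53375 in senescent whole cells and mitoplasts.

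**Figure D2:**
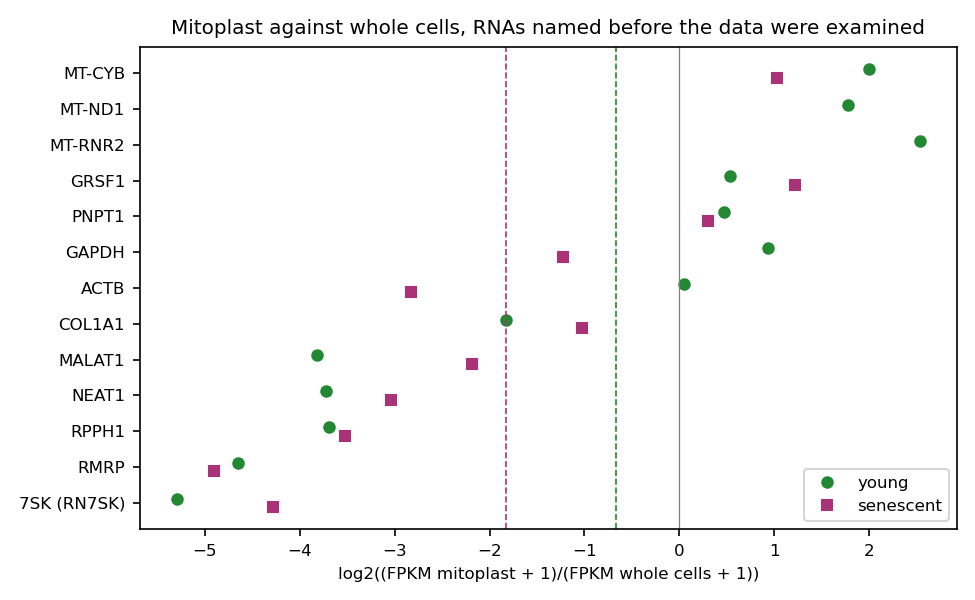
Log2 ratio of FPKM (pseudocount 1) in mitoplast against whole cells for RNAs with an estimate above 0 in both libraries, in young (circles) and senescent cells (squares). Each point sets 1 mitoplast library against 1 whole cell library. Dashed lines are the medians of nuclear-encoded genes, −0.67 in young and −1.83 in senescent cells. MT-CYB lies right of 0 in both ages, and RMRP, RPPH1 and 7SK lie left of −3.

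Cytosolic mRNAs remained abundant in young mitoplasts. GAPDH was at 953 FPKM in young whole cells and 1818 in young mitoplasts, and ACTB, encoding beta-actin, at 5349 and 5529.5. The corresponding senescent values were 863 and 368 for GAPDH and 3786 and 533 for ACTB. In young cells, oxidative phosphorylation subunits had a median mitoplast to whole cell ratio of 0.55, cytosolic ribosomal proteins 0.51 and mitochondrial ribosomal proteins 0.24, each above all 10000 random lists, though rescaled over all genes they turned to −0.07, −0.11 and −0.35. The tricarboxylic acid cycle stood at 0.36 (99.6th percentile), RNA synthesis and processing factors at 0.14 (99.3th) and import at 0.11 (98.2th). Lists that are not mitochondrial also lay above most random lists, glycolysis at 0.43 (97.9th) and histones at 0.12 (98.0th). These 5 also turned below 0 with that rescaling. The median nuclear-encoded gene stood at −0.67. Relative to it, oxidative phosphorylation subunits stood at 1.22, cytosolic ribosomal proteins at 1.18 and mitochondrial ribosomal proteins at 0.91. RPS14 was at 110 and 311 FPKM and LDHA at 300.4 and 723, the latter led by a nonsense-mediated-decay transcript (45.3%). Several lists of secreted and endoplasmic reticulum proteins were at the other end. Matrix proteins had a median of −1.79 (0.02th percentile), with 35 of 42 lower by 1 or more, growth factors −1.50 (1.32th), proteases −1.50 (2.58th) and endoplasmic reticulum stress genes −1.34 (3.58th), while cytokines and chemokines, at −1.08 (14.3th), lay within the random lists. In senescent cells matrix, protease and endoplasmic reticulum stress lists lay in the middle of the random lists, at the 51.3th, 64.1th and 38.2th percentile. There, growth factors lay at the 2.65th percentile and cytokines and chemokines, with a median of −2.62, at the 1.71th. In young cells COL4A2 was at 700.3 and 49.8 FPKM, TNC at 138 and 20.8, MMP2 at 819 and 83.7 and COL1A1 at 1501 and 424. GRSF1 was at 6.11 FPKM in young whole cells and 9.29 in young mitoplasts and PNPT1 at 5.75 and 8.37. These log2 ratios, 0.53 and 0.47, are below that of oxidative phosphorylation subunits, which rescaling over all genes turned below 0. In senescent cells GRSF1 was at 6.33 and 16.0 and PNPT1 at 5.14 and 6.58. GRSF1 lay mainly in a retained-intron transcript of 3561 nt in young mitoplasts and senescent whole cells, and in one of 419 nt without a coding frame in senescent mitoplasts. PNPT1 was led by nonsense-mediated-decay transcripts in both young libraries and by a retained-intron one in senescent mitoplasts, so the ratios of these 2 genes need not follow their coding mRNAs.

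Of 10366 genes compared in young cells, 901 were higher and 2719 lower in mitoplasts by a log2 ratio of 2 or more, and 508 and 3396 after rescaling over all genes. Of the 10366, 901 were listed at 0 in mitoplasts and 520 in whole cells, and each of these passes the threshold before rescaling. The lowest 12 were TANC2, AKAP13, RREB1, FOXP2, LTBP1, MGAT5, EGFR, PIK3CA, PRKG1, RNF217, ZDHHC17 and PPP4R2. Their whole cell values came mostly from short or assembled transcripts: EGFR at 778 FPKM in young whole cells was carried by a transcript of 561 nt without a coding frame, and turned to 2.07 with protein-coding transcripts alone, as RNF217 did to 1.16. PIK3CA at 614 and AKAP13 at 928 FPKM were carried by transcripts typed as coding, of 245 and 322 nt. The highest 12 were FGF22, FOCAD-AS1, DMD, SLCO5A1, FOXC2, PTPRT, RBFOX1, RAP1GAP, NTRK3, HFM1, ESR1 and RAB11FIP2. SLCO5A1, at 5.45 and 393 FPKM, and FOXC2, at 4.13 and 282, were carried by coding transcripts of 2630 and 2478 nt, while FGF22 rested on an assembled transcript and turned to −0.94 with annotated transcripts alone, as RBFOX1 did to −0.19.

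In senescent cells, 10260 genes were compared, with 1327 higher and 4875 lower in mitoplasts. Of the 10260, 2497 were listed at 0 in mitoplasts and 664 in whole cells, and each of these passes the threshold. Scaled by the median of ratios the split was 1869 and 3323. The median nuclear-encoded gene stood at −1.83. Cytosolic ribosomal proteins, at a median of −0.55, lay above all random lists, and the median turned to 0.06, 0.23 and 0.38 under the 3 rescalings, whereas oxidative phosphorylation subunits, at −1.33, lay at the 66.2th percentile and mitochondrial ribosomal proteins, at −2.11, at the 13.8th. Mitosis genes had a median of −0.05, above all random lists, which turned to 1.59 with median-of-ratios scaling, with 15 of 31 higher and 13 lower: BUB1B was at 0.634 FPKM in senescent whole cells and 21.4 in mitoplasts and HMMR at 0.342 and 20.0, with 93.7% and 86.7% of the mitoplast values in transcripts of 526 and 528 nt without a coding frame. Members under 1 FPKM in whole cells, such as these 2, were measured only through a high mitoplast value. The number higher, the median and its percentile are therefore partly set by that rule. The highest included ZBTB7C, RBFOX3, VWA3B, PTPRT, CCDC85B, LINC01402, ATP2A1, PLPPR5, ESRRG, REPS2 and FCHO1, of which CCDC85B, at 13.4 and 873 FPKM, was led by a coding transcript of 1524 nt and each of the others named by one shorter than 600 nt. With protein-coding transcripts alone, ESRRG, FCHO1, PLPPR5 and REPS2 turned to −0.07, −0.34, −0.07 and −0.01. The lowest were LCOR, RBMS3, USP53, TLE4, DYRK1A, CDC42SE2, HMGA2, EGFR, RIN2, MEG3, PCCA and BCR, of which EGFR turned to 1.14 with protein-coding transcripts alone and MEG3 to 4.10 with annotated transcripts alone.

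Senescent and young mitoplasts differed more widely than whole cells of the same ages. Of 9155 genes, 2199 were higher and 4770 lower in the senescent mitoplast library, and the median nuclear-encoded gene stood at −1.14. Of the 9155, 1913 were listed at 0 in the senescent and 727 in the young mitoplast library, and each of these passes the threshold. The split depended on scaling, with 4180 higher and 2255 lower after rescaling over all genes, 3727 and 3643 over nuclear-encoded genes, and 2790 and 3789 by the median of ratios. Oxidative phosphorylation subunits had a median of −2.59 with 53 of 71 lower, mitochondrial ribosomal proteins −2.36 with 58 of 73, cytosolic ribosomal proteins −2.10 with 74 of 77 and mitosis genes −2.60 with 34 of 43, all below all 10000 random lists. RPS14 was at 311 FPKM in young and 17.8 in senescent mitoplasts, and PLK1, a mitotic kinase, at 60.7 and 0.152. COX6A1, a subunit of cytochrome c oxidase, was at 165 and 0.114 FPKM, and NDUFB10, of complex I, at 157 and 0.150. The senescent values of PLK1, COX6A1 and NDUFB10 lie near the floor of a library that may hold few molecules, as described below. A loss of these mRNAs therefore cannot be told apart from a failure to sample them. Growth factors and IGF-binding proteins had a median of 0.26 (98.4th percentile) with members in both directions, 6 of 23 higher and 9 lower by 1 or more; IGFBP7 was at 34.2 and 263 FPKM and IGFBP3 at 5.84 and 40.5. The lowest 12 were LCOR, PRRX1, CDC42SE2, COX6A1, NUDCD3, NDUFB10, NAA38, EMP1, FZD2, RPL22L1, PSMC1 and ARHGEF2. The highest 12 were XYLT2, SFXN4, SSR1, ITPR1, NKTR, AKAP13, REPS2, PIK3CA, IPO8, TRPC6, SLC12A9 and COL10A1, whose leading transcripts were each under 600 nt; SFXN4 turned to −0.05 and TRPC6 to −1.12 with protein-coding transcripts alone. Of coding genes at 50 FPKM or more in young whole cells, 9.87% were listed at 0 in the senescent mitoplast library and 2.94% in the young mitoplast library.

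The fraction ratio was also compared between ages. Of 7977 genes, 1453 had a higher centred mitoplast to whole cell ratio in senescent cells by 2 or more and 1038 a lower one, against 1261 and 1417 with median-of-ratios scaling, 1271 and 1578 after rescaling over all genes and 1368 and 1567 over nuclear-encoded genes. A pseudocount of 0.1 gave 1624 and 2017, and genes above 0 in all 4 libraries and outside shared loci 1118 and 367. The highest differences were in DAB2IP, CCDC85B, XYLT2, SLC35E3, PRKG1, AKAP13, SFXN4 and SLC12A9, and the lowest in COX6A1, LCOR, NUDCD3, PSMC1, CDC42SE2, TIMM50, NAA38 and FZD2. TIMM50, a subunit of the inner membrane import complex, was at 19.9, 24.6, 82.2 and 0.522 FPKM in young whole cells, senescent whole cells, young mitoplasts and senescent mitoplasts. Over 2844 coding genes at 5 FPKM or more in all 4 libraries, the fraction ratios of the ages had a Spearman correlation of 0.43 and the senescence ratios of the fractions one of 0.28; these are correlations across genes, which are not independent replicates.

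**Figure D3:**
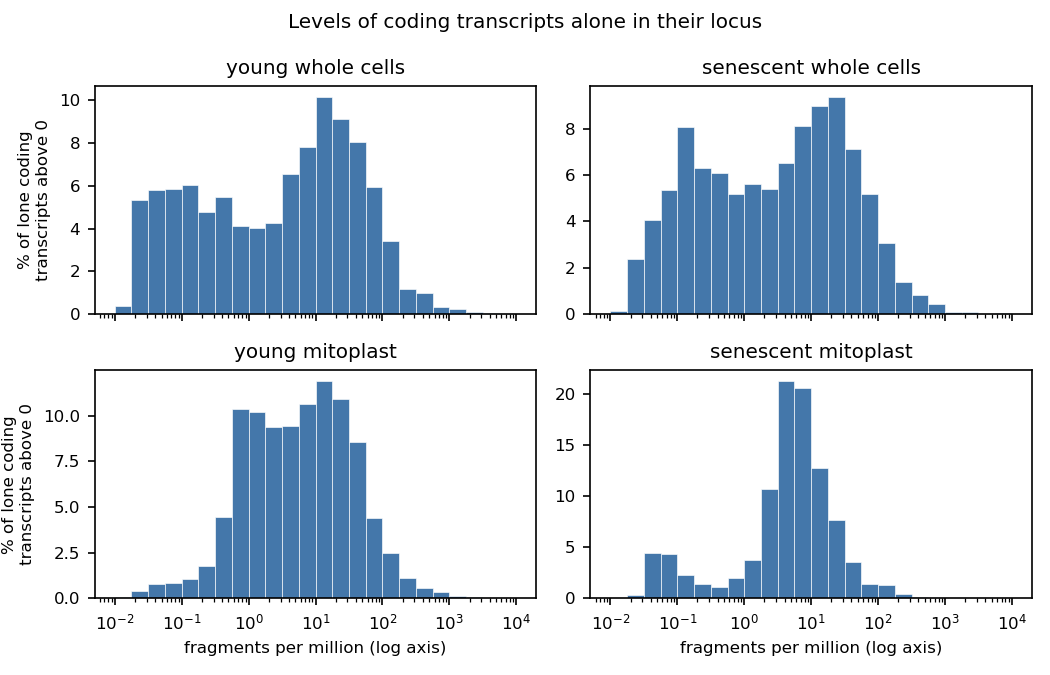
Distribution of coding transcripts that are alone above 0 in their locus, at least 600 nt long, by FPKM times length in kilobases (fpm, log axis), as a percent of such transcripts in each library. Whole cell libraries spread below 0.3 fpm, with 27.5% and 25.8% of transcripts there, against 4.71% and 12.9% in the young and senescent mitoplast libraries.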

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

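The tests of few molecules in the senescent library and of transcript length and mitochondrial localisation were set out before their results were seen; all other tests here were chosen after the patterns had been seen. The pattern of few molecules was divided into a senescent and a young part after a first test, which had required a raised floor in both mitoplast libraries, had been seen.

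Values of coding transcripts in the senescent mitoplast library formed separate groups, with 12.9% of lone transcripts under 0.3 fpm (FPKM times length in kilobases), 3.32% between 0.3 and 1 and 83.8% at 1 or more. If few RNA molecules had entered the library and been copied many times, transcripts at 1 to 20 fpm in senescent whole cells would be missed by chance. Of 356 such transcripts 35.4% were seen, against 31.3% predicted from a level of 3.53 fpm per molecule and 99.9% predicted from the lowest values. Lower depth would raise the floor, and the 5th percentile was only 1.23 times that of senescent whole cells. At 0.057 fpm, however, it lay inside the small group under 0.3 fpm. Such low values were thus recorded in this library. Neither that percentile nor the prediction from the lowest values describes the larger group at 1 fpm or more. Failed estimates would also remove abundant transcripts, of which 0% (52 at 50 fpm or more) were listed at 0 against 59.3% at 1 to 20 fpm. This covers only transcripts alone in their locus. Of all coding genes at 50 FPKM or more in young whole cells, 9.87% were listed at 0 in the senescent mitoplast library, so failed estimates stay open for other loci. Few input molecules may underlie the senescent mitoplast ratios, and lower depth is not excluded. In the young mitoplast library the 5th percentile was 11.3 times that of whole cells, as lower depth would give, and the 85.8% seen lay below both predictions, 89.7% from molecules and 98.9% from the lowest values, so few molecules cannot be told apart from depth there; a change in the RNA of senescent mitochondria stays open and untested.

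Most mitochondrial mRNAs were listed at 0 in the senescent libraries. Of 23 such values, 91.3% lay in a locus with a spanning assembled transcript, in line with reads being assigned to it. Whether these mRNAs were lost in senescent cells cannot be decided here. That transcript stood 1.59 log2 units above the young median of the 13 mRNAs in whole cells and 0.70 above it in mitoplasts. But in senescent mitoplasts its locus also held the rRNA MT-RNR2, and the files hold no coordinates. Its reads may therefore not come from the mRNAs. The median ratio of mitochondrial mRNAs between fractions was 1.89 in young and −6.33 in senescent cells over 2 measured members. The senescent median rests on MT-ND1 being listed at 0 in senescent mitoplasts. The 2 medians are given because their directions are opposite, a difference that was not tested.

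In young cells, lists of mRNAs for mitochondrial proteins lay above most random lists in mitoplasts, as did glycolysis (0.43, 97.9th percentile) and histones (0.12, 98.0th), which are not mitochondrial. Among random lists matched on expression and on the longest annotated transcript, oxidative phosphorylation subunits still lay at the 100th percentile. This cannot decide on length, since the longest annotated transcript can exceed the one expressed. The list's median was 1426 nt, while COX6A1 and NDUFB10, for example, were led by transcripts of 572 and 705 nt in young mitoplasts. Cytosolic ribosomal proteins also lay at the 100th percentile, so retention of mitochondrial mRNAs at the organelle would not account for every raised list. Matrix proteins lay at the 0.27th. Carry-over of cytosolic mRNA that spares mRNAs made at the endoplasmic reticulum was not tested and stays open.

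Other lists also changed sign between the ages, but among nuclear-encoded lists only 2 did so with a median fraction ratio of 0.5 or more in size in both ages, and the differences were not tested. Oxidative phosphorylation subunits stood at 0.55 in young and −1.33 in senescent cells, and cytosolic ribosomal proteins at 0.51 and −0.55, though rescaling over all genes turned the young medians to −0.07 and −0.11 and the senescent ribosomal one to 0.06. Relative to the median gene, ribosomal proteins stood at 1.18 in young and 1.28 in senescent cells, so their change of sign follows the shift of that gene from −0.67 to −1.83, and oxidative phosphorylation subunits at 1.22 and 0.50. LMNB1 had a fraction ratio of −2.03 in young and 2.53 in senescent cells, also untested, but the signs compare different transcripts: the young mitoplast value lay in an assembled transcript, and the senescent one, 7.73 FPKM, in a transcript of 557 nt without a coding frame. Assembled transcripts held 92.7% of the summed FPKM in young and 97.3% in senescent mitoplasts, above the 53.7% and 76.2% in whole cells. Of the 32046 and 8645 above 0 in mitoplasts, 3443 and 1422 were placed in 1 gene and entered gene values, and the others entered no gene value.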

How the results depend on the processing

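Annotated transcripts alone, protein-coding transcripts alone, the filter of 20 FPKM, and members or genes above 0 outside shared loci were chosen after the data had been seen. Of the alternatives planned, the authors' intervals were not run, since the files used here hold none, and the length-weighted share was not run for the senescent libraries, since the length of the spanning transcript is not in the files. Weighted by length over annotated transcripts, the young shares were 12.7% in whole cells and 43.4% in mitoplasts. Counts of genes stayed within 1.5 times under the pseudocount of 0.1, the 3 rescalings, annotated transcripts alone and the removal of small RNAs, though the rescalings moved the split between higher and lower. For the difference of fraction ratios, 1453 higher and 1038 lower turned to 1624 and 2017 with the pseudocount and were 1118 and 367 for genes above 0 outside shared loci. Among counts and shares 44 alternatives stayed and 17 moved; among list medians 671 stayed, 220 moved and 29 reversed; among named genes 2394 stayed, 1175 moved and 33 reversed. The cause was not tested, except that a filter or subset changes the number of genes compared. The reversed tallies do not cover every change of sign. Each list counted as reversed had a main median in the tails of its random lists. In the young fraction comparison, rescaling over all genes took import from 0.11 to −0.46, counted as reversed. The actin cytoskeleton list (0.12, 91.1th percentile) and ACTB (0.05) also lay near 0 there and were not counted. Small values may therefore change sign outside these tallies. Low values are limited by an unknown depth.

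Genes past the threshold numbered 2457 in whole cells, 4391 between mitoplasts, 2019 in the young and 3900 in the senescent fraction comparison and 1593 for the difference of fraction ratios with protein-coding transcripts alone. With the filter of 20 FPKM they were 1996, 2965, 2037, 2846 and 1094. Above 0 outside shared loci they were 4186 between mitoplasts, 2106 and 2950 between fractions and 1485 for the difference. Between mitoplasts there were 11247 with a filter of 1 FPKM and 11247 with none, and the difference counted 6180 with none.

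For members above 0 outside shared loci, few mitochondrial RNAs were left. Medians of mitochondrial mRNAs turned to 1.74 in whole cells (2 members), 0.82 between mitoplasts (1) and 1.03 in the senescent fraction comparison (1). Those of tRNAs turned to 1.23 in whole cells (3), 3.33 in the young (3) and 4.39 in the senescent fraction comparison (1). RNA-processing factors turned to −0.0349 in the young and mitosis to 1.10 in the senescent fraction comparison. In the young fraction comparison, rescaling over all genes turned oxidative phosphorylation to −0.0706, mitochondrial ribosomal proteins to −0.35, RNA-processing factors to −0.40, import to −0.46, the tricarboxylic acid cycle to −0.22, glycolysis to −0.14, cytosolic ribosomal proteins to −0.11 and histones to −0.47. Over nuclear-encoded genes, RNA-processing factors were −0.0111, import −0.0496 and histones −0.0374, and with protein-coding transcripts alone RNA-processing factors were −0.0396 and the tricarboxylic acid cycle −0.00599. In the senescent fraction comparison, cytosolic ribosomal proteins turned to 0.0600 over all genes, 0.23 over nuclear-encoded genes and 0.38 by median of ratios. Mitosis turned to 1.59 by median of ratios, 1.90 for members at 5 FPKM and 1.06 with protein-coding transcripts alone, and epithelial markers to −1.03 over all and −1.04 over nuclear-encoded genes.

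With annotated transcripts alone, CHCT1 turned to −1.86, MEG3 to −6.03 and ZNF718 to −0.56 in whole cells, NEAT1 to −1.87 and TPM4 to 4.03 between mitoplasts, FGF22 to −0.94, LOXL1 to 4.25 and RBFOX1 to −0.19 in the young and LOXL1 to 3.64 and MEG3 to 4.10 in the senescent fraction comparison. With protein-coding transcripts alone, CHCT1 was −1.86, MAN2B1 0.11, SERPINF1 1.91 and ZNF718 −0.56 in whole cells, and ATP6V1H −2.70, SFXN4 −0.0476, TPM4 4.03, TRPC6 −1.12 and VWF −0.15 between mitoplasts. In the young fraction comparison EGFR was 2.07, FGF22 −0.94, IL7 0.53, LOXL1 4.25, RBFOX1 −0.19 and RNF217 1.16, and in the senescent one EGFR 1.14, ESRRG −0.0666, FCHO1 −0.34, LOXL1 3.64, PLPPR5 −0.0738 and REPS2 −0.00666. Rescaling over all genes turned CCL2 to 0.18 and CDKN1A to 0.11 between mitoplasts.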

Other observations

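Long noncoding RNAs differed singly in whole cells. MEG3, an imprinted noncoding RNA, was at 242 FPKM in young and 3061 in senescent whole cells, mainly in assembled transcripts, and its log2 ratio was 3.65, against −6.03 with annotated transcripts alone. PURPL and CASC6 were among the highest ratios, with CASC6 at 0.217 and 38.1 FPKM. Among glycolytic genes SLC2A1, encoding the glucose transporter GLUT1, was at 22.3 and 83.8 FPKM and PFKP at 66.4 and 14.6. In the cytoskeleton list CALD1, encoding caldesmon, was at 683 and 2742 FPKM.

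Within coding genes, the share of annotated FPKM in transcripts typed as processed, without a coding frame, was 21.4% in young whole cells, 21.0% in senescent whole cells, 22.1% in young mitoplasts and 43.5% in senescent mitoplasts. In young cells, 970 coding genes led by such a transcript in whole cells had a median mitoplast to whole cell ratio of −1.45, and 4709 led by a coding transcript one of −0.43. In senescent cells the corresponding medians were −1.83 and −1.28. The genes were grouped by their whole cell library, which is also the divisor of the ratio. Part of these differences can therefore come from the grouping itself.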
